A study of Mus musculus with 60 samples.

How the data were processed

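Epididymal white adipose tissue of male mice, either wild type (WT) or lacking the clock gene Bmal1 in the liver (KO), was profiled by bulk Smart-seq3, a full-length cDNA method run here on tissue RNA. The labels place 60 libraries in 12 groups of 5, with 2 genotypes sampled at 6 zeitgeber times (ZT) 4 h apart. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between libraries, which may be technical.

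The authors deposited whole-number counts per feature, 1 column per library, with no normalization. Per the file headers, the columns come from sorted, deduplicated alignments. Per the submitters' processing notes, STAR 2.5.4b was used with the mm10 (GRCm38) assembly. The counting program, its annotation, the use of strand, and whether duplicates were removed by molecular identifier or by position are not given in the sources used here. The labels' protocols list several read formats and instruments, and which of them these libraries had is not given in the sources used here. The table has 180 columns, of which 120 matched no library of the series by name and were not used. It has 32377 rows, 6939 of them with no count in the 60 libraries.

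The files do not pair the rows with gene names or identifiers. A row is therefore called here by its place among the data lines of the deposited table, and no name was taken from the order of a reference annotation. The gene lists, the clock genes and the cell type markers chosen before the data were examined could not be applied, and no enrichment or gene set test was run. The deleted gene could not be looked up in the libraries either, so the genotype labels were not checked against the counts; the deletion is in liver, while fat was sequenced. The naming rule set before the data were examined skips features without a name, so it skipped all that passed. At most 2 rows in each direction are given per comparison, those with the smallest p, and each was chosen after its values were seen.

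Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Rows were kept by the filterByExpr rule on the 12 groups, which left 6030 rows holding between 66.7% and 90.2% of each library's counts, and libraries were scaled by the trimmed mean of M-values (TMM). The rhythm model had a mean per genotype and a cosine and a sine term with a 24 h period per genotype, fitted to all 60 libraries by quasi-likelihood with robust dispersion. F tests addressed the WT rhythm, the KO rhythm, the difference between them, and the genotype term as the level over the day. A second model with 12 group means gave the KO minus WT contrast at each ZT. P-values were adjusted by the Benjamini-Hochberg method over the 6030 rows, with a threshold of 0.05. Amplitude (from the mean to the peak, log2) and peak time came from least-squares cosinor fits to log2 CPM (counts scaled to a common library total) with a prior count of 2, with delta-method standard errors.

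The alternatives fixed before the data were examined were other scalings, other low-count filters, DESeq2 1.42.0, a replicate block, the number in the library name as a factor, the total count as a covariate, leaving out each library and the shallow libraries, time as a factor, model choice by the Bayesian information criterion, and stricter thresholds. Libraries were left out with the 6030 rows held fixed unless stated, except that the fit to the 39 libraries left without those standing apart and the shallow ones tested 6018 of them. Further alternatives chosen after seeing the data leave out libraries that stand apart or have under 10000 counts, use principal components as covariates, or keep rows seen in 90% of the libraries with at least 10000 counts and leave out the rest. Before these were kept, many other fits had been looked at, with other numbers of components (also computed on residuals), other shares of libraries a row had to be seen in, other sets of libraries and other partings on the first component, and the values of those fits are not given. The component used to part the libraries was computed on log2 CPM of the 58 libraries with at least 10000 counts. The libraries above the widest gap in the scores of this first component are called the libraries standing apart. The components used as covariates were computed on log2 CPM of all 60 libraries, so they are not the one used for that parting.

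The models were tested on simulated counts with the real means, dispersions and library sizes over 6030 rows. Of 100 rows given a WT rhythm with an amplitude of 1 (log2), 58 were recovered, and 89 of 100 with an amplitude of 2. For the KO rhythm 62 and 98 of 100 were recovered, for the rhythm difference 42 and 88, and for a level change of 1 and 2 (log2) 67 and 94. At ZT0, 54 of 100 changes of 2 (log2) and 86 of 100 changes of 4 were recovered. At ZT4, ZT8, ZT12, ZT16 and ZT20, 56, 46, 40, 54 and 43 of 100 changes of 2 (log2) were recovered. The first 5 of these simulations also called 20, 31, 35, 30 and 7 unchanged rows for the WT rhythm, the KO rhythm, the difference, the level and ZT0. Unchanged rows were thus 11.98%, 16.2%, 21.2% and 15.7% of the calls for the WT rhythm, the KO rhythm, the difference and the level, so the threshold of 0.05 was not held in these 4 tests, and 4.76% at ZT0. In 20 simulations with no changed row, the median number of calls was 2 (highest 6) for the WT rhythm, 2.5 (highest 8) for the KO rhythm, 4 (highest 13) for the difference, 1 (highest 8) for the level and 0 (highest 0) at ZT0. Simulated libraries vary independently from row to row, which real libraries do not. Both sizes of change of a comparison were put into the same run. The recovered numbers and the shares of unchanged rows among the calls also depend on how many changed rows were put in.

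Total counts ranged from 1502 to 1677090 per library, and the median count per tested row within a library ranged from 0 to 64. Shares of a library's counts carry 95% Wilson intervals, and a share of 0 allows up to 3 counts of the total; both cover counting error only. No library pair of a group agreed within sampling noise: the lowest chi-square per degree of freedom of any pair was 1.23, in KO ZT8.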

Results

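The series asks how loss of the liver clock affects daily rhythms of gene expression in white fat. Messenger RNA of epididymal white adipose tissue was counted in 30 WT and 30 KO libraries, 5 per genotype at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20. KO stands for mice that lack Bmal1, a core transcription factor of the circadian clock, in the liver. The median total was 154896 counts, with 138496 in WT and 180954 in KO libraries. WT ZT12 replicate 3 had 1502 counts and WT ZT8 replicate 2 had 3996, while the remaining libraries had at least 40959. The number of rows with a count ranged from 727 to 20757 per library.

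The libraries fell into separate sets by their overall profile. The first principal component took 40.4% of the variance over the 58 libraries with at least 10000 counts. In its scores, 19 libraries lay between 38.9 and 95.3 and the other 39 between -48.4 and 8.45. The 19 libraries standing apart comprised 12 WT and 7 KO libraries: 4 of 5 at WT ZT16, 3 of 5 at WT ZT12 and at KO ZT0, 2 at WT ZT0 and KO ZT20, 1 at WT ZT4, WT ZT8, WT ZT20, KO ZT4 and KO ZT12, and 0 at KO ZT8 and KO ZT16. The mean score was 11.4 in WT and -10.7 in KO, and the mean of the differences within ZT, KO minus WT, was -22.7 (two-sided permutation test within ZT, 100000 resamples, p = 0.0905).

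**Figure D1:**
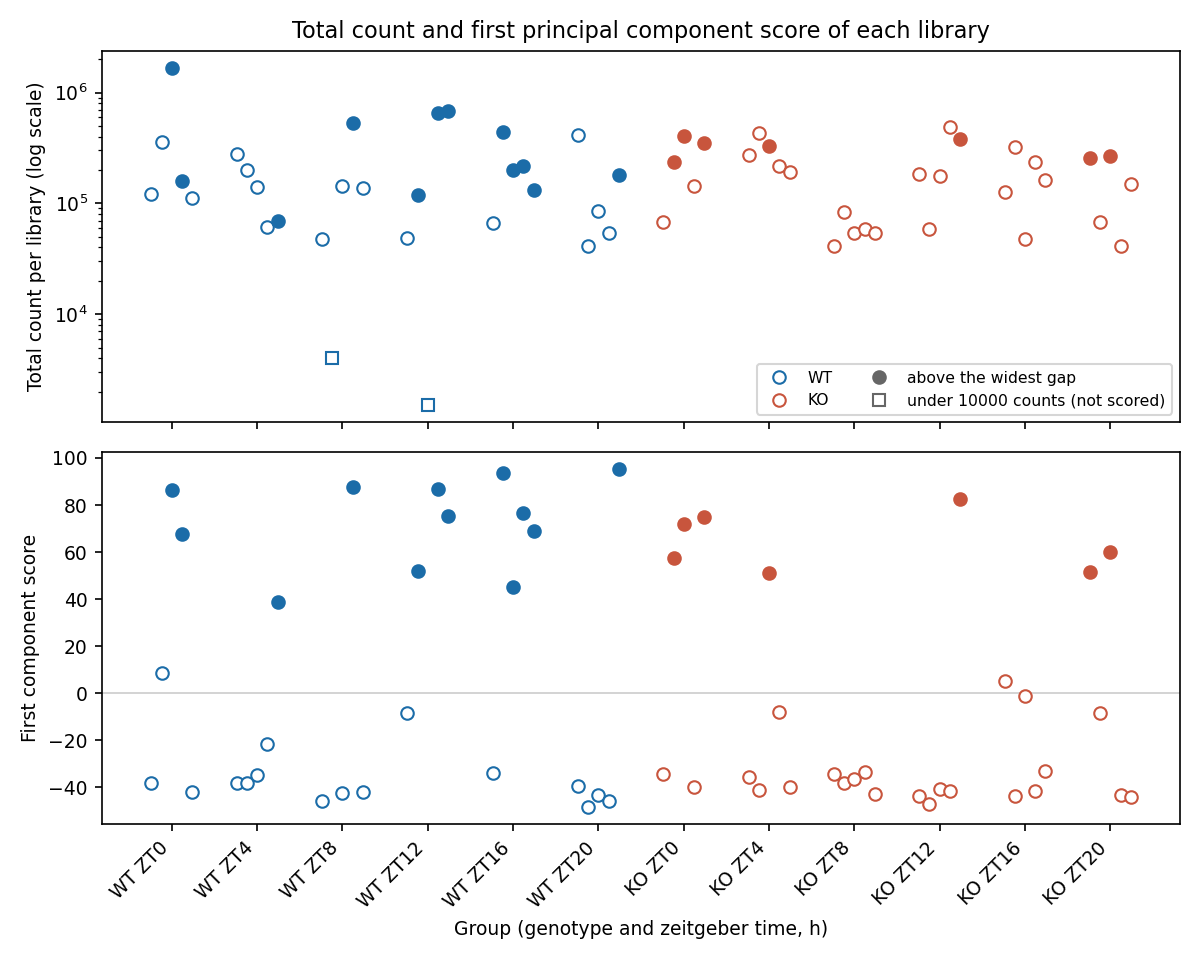
Total count (top, log axis) and first component score (bottom) of each of the 60 libraries by group; circles are libraries, squares the 2 libraries under 10000 counts, and filled symbols the 19 libraries above the widest gap. The filled symbols lie between 38.9 and 95.3 and the scored open ones between -48.4 and 8.45.

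Part of this split could be seen in single rows of the table. The shares and library numbers given here are over the 58 libraries with at least 10000 counts. Table row 22244 held 2.01% to 4.61% of all counts in 12 of the 19 libraries standing apart, and at most 0.308% in the other 46 libraries, 7 of which also stood apart. In WT ZT0 replicate 4 its share was 4.61% (95% Wilson interval 4.51% to 4.71%) and in KO ZT0 replicate 3 it was 4.47% (4.41% to 4.54%). Of the 12 libraries, 9 were WT and 3 were KO. Table row 4274 held the largest median share, 2.57%, and reached 1% in 39 libraries, of which 1 stood apart. Table row 3911 did not follow the split: it held 10.4% to 11.5% of the counts in 1 WT library that did not stand apart and 1 KO library that did, and at most 0.305% in the other 56.

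A 24 h rhythm was called for 17 of 6030 rows in WT (edgeR quasi-likelihood test, adjusted p under 0.05). Their median amplitude was 0.93 on the log2 scale, with a range of 0.53 to 1.38, and 11 of them peaked between ZT18 and ZT2, 5 between ZT2 and ZT10 and 1 between ZT10 and ZT18. In table row 20125 the mean rose from 28.2 ± 17.2 CPM at ZT0 to 195 ± 118 CPM at ZT8 and was 8.30 ± 8.82 CPM at ZT20 (SD, n = 5). The ZT20 mean rests on 0 to 5 counts per library. Its fitted amplitude in WT was 1.38 ± 0.26 (SE, log2) with a peak at 7.40 ± 0.708 h, and its adjusted p was 0.000618. That amplitude fit weighted WT ZT12 replicate 3, with 1502 counts in total and 0 of this row, like any other library. In the 39 libraries neither standing apart nor under 10000 counts, the amplitude was 1.83 in WT and 1.77 in KO. The peaks there were at 8.91 h and 8.76 h. Table row 9164 followed with an amplitude of 1.36 ± 0.24, a peak at 3.30 ± 0.686 h and an adjusted p of 0.0161. With the libraries standing apart and those under 10000 counts left out, 37 rows were called, 10 of them among the 17; with the rows also chosen again among the 39 libraries left, 11 of 2408 rows were called, 1 of them among the 17. The count was 6 without WT ZT12 replicate 2 and 47 without WT ZT0 replicate 4. The smaller set of libraries holds 1 WT library at ZT12 and 1 at ZT16, which are taken to vary like the others. On simulated counts 11.98% of the calls of this test were unchanged rows, a share that depends on how many changed rows were put in. With the times shuffled within genotype the median count was 9, and 39 of 100 splits, the real one included, gave at least 17.

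In KO, 41 rows were called rhythmic, with a median amplitude of 0.90 (log2; range 0.33 to 1.74). The peak fell between ZT18 and ZT2 in 36 of them, and 3 of 5 KO libraries at ZT0 and 2 of 5 at ZT20 stood apart, against 0 at ZT8 and ZT16. Table row 20125 again had the smallest p: its mean was 16.8 ± 10.6 CPM at ZT0, 180 ± 52.5 CPM at ZT8 and 11.5 ± 13.8 CPM at ZT20 (SD, n = 5). Its amplitude in KO was 1.74 ± 0.22 and its peak at 8.80 ± 0.484 h, with an adjusted p of 0.000585. In table row 12236 the KO mean was 146 ± 49.2 CPM at ZT8 and 9.63 ± 10.2 CPM at ZT20, with an amplitude of 1.36 ± 0.23 and an adjusted p of 0.0214. These means rest on 6 to 9 counts per library at ZT8 and 0 to 5 at ZT20. The row kept its KO rhythm in 11 of 13 other settings of the model. It lost it without libraries under 51632 counts and with the library-name number as a factor. The count of 41 moved to 732 when KO ZT12 replicate 5, a library standing apart, was left out, and to 7 when any 1 of 9 other KO libraries was left out. The 732 rows followed the first component more closely than most, with a median absolute correlation of 0.734 against 0.462 over all tested rows. Without the libraries standing apart and those under 10000 counts the KO count was 132, 24 of them among the 41, or 8 with the rows chosen again, 3 of them among the 41. On simulated counts 16.2% of the calls of this test were unchanged rows, a share that depends on how many changed rows were put in. With the times shuffled within genotype the median count was 9, and 18 of 100 splits, the real one included, gave at least 41.

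Rhythm was called in both genotypes for 7 rows. Lists of independent rows would share 0.116, but rows vary together, and 35 of 100 shuffles of the times within genotype, the real order included, gave at least 7. Over these 7 rows the median amplitude was 0.78 in WT and 0.65 in KO, and the median log2 ratio of amplitudes, KO over WT, was 0.19. Of 100 draws with the genotype shuffled within ZT, 88 gave a ratio at least as far from 0. The mean peak time differed by -4.09 h (KO minus WT, range -7.21 to 1.40 h), and 73 of the 100 draws gave a difference as large. Table row 20125 passed in both genotypes when each of the 60 libraries was left out in turn. Its rhythm difference between the genotypes was not called (adjusted p = 0.380). The preceding row of the table, 20124, was also called in KO, with an amplitude of 0.88 ± 0.18, a peak at 8.48 ± 0.791 h and an adjusted p of 0.0456. In WT it was not called (adjusted p = 0.206). The following row, 20126, was called in neither genotype (adjusted p = 0.707 in WT and 0.828 in KO). Without names, reads shared by overlapping features remain possible for rows 20124 and 20125.

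**Figure D2:**
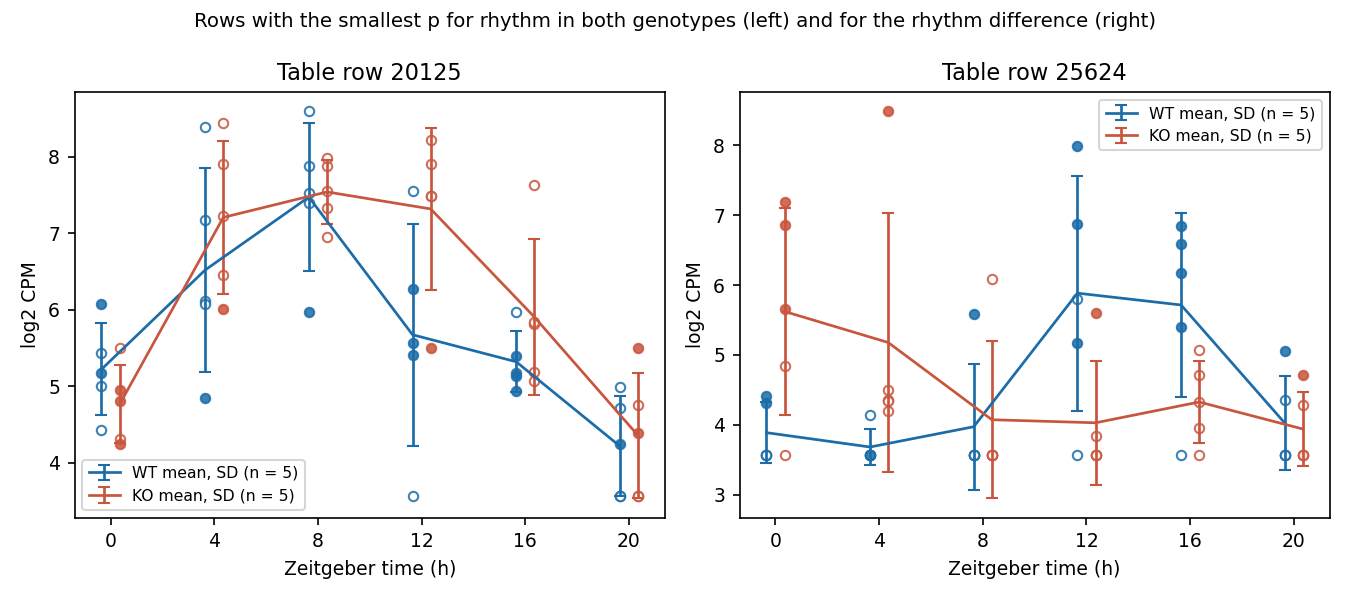
Log2 CPM of table row 20125 (left) and table row 25624 (right) against zeitgeber time in hours; points are libraries (filled: the 19 standing apart), lines join the means of 5 libraries in WT (blue) and KO (red), and bars are SD. Row 20125 has its highest mean at ZT8 in both genotypes. Row 25624 is at its floor in many open libraries and, among the filled ones, in WT ZT4 replicate 5 and KO ZT20 replicate 3. Its highest value, 8.48 in KO ZT4 replicate 3, is a filled one.

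The test of the difference between the genotypes addressed whether fat rhythms depend on the liver clock. It called 32 rows, of which 31 were called rhythmic in neither genotype and 1, table row 25624, in WT. Table row 25624 had the smallest p (adjusted p = 0.000795): in WT its mean was 83.4 ± 97.4 CPM at ZT12 and 1.14 ± 2.56 CPM at ZT4, and in KO it was 7.81 ± 16.1 CPM at ZT12 and 76.1 ± 151 CPM at ZT4 (SD, n = 5). Its fitted peak was at 14.1 ± 0.875 h in WT, with an amplitude of 1.16 ± 0.27, and at 1.57 ± 1.65 h in KO, with an amplitude of 0.71 ± 0.31. Table row 22108 came next (adjusted p = 0.0137), with peaks at 13.8 ± 0.933 h in WT and 0.894 ± 2.11 h in KO. The WT peaks of both rows fell near the times at which 3 of 5 (ZT12) and 4 of 5 (ZT16) WT libraries stood apart, and the KO peaks near ZT0, where 3 of 5 KO libraries did. Both rows had at most 3 counts in any library not standing apart. In KO ZT4 replicate 3 and WT ZT12 replicate 4, which stood apart, row 25624 had 92 and 55 counts and row 22108 had 151 and 70. Some libraries standing apart were low too: row 25624 had 0 counts in WT ZT4 replicate 5 and KO ZT20 replicate 3. Without the libraries standing apart and those under 10000 counts, 15 rows were called, 0 of them among the 32, and with the rows chosen again 0 were called by edgeR. The count was 1 without WT ZT12 replicate 2 or without KO ZT4 replicate 3, and 711 without KO ZT12 replicate 5. On simulated counts 21.2% of the calls of this test were unchanged rows, a share that depends on how many changed rows were put in. With the genotypes shuffled within ZT the median count was 1, and 18 of 100 splits, the real one included, gave at least 32.

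The level over the day was called different in 0 rows, neither higher nor lower in KO, by edgeR and by DESeq2. At an unadjusted p under 0.05 edgeR gave 198 rows higher and 571 lower in KO, where 301.5 are expected by chance over both directions. The smallest adjusted p was 0.0662. With no low-count filter edgeR called 38 rows higher and 1070 lower, and with the first 3 principal components as covariates 21 higher and 1 lower. Table row 11672 had a log2 fold change, KO minus WT, of -3.58 ± 0.78 (SE), and table row 22987 one of 0.68 ± 0.18, both at that adjusted p. Row 11672 had 383 counts in WT ZT0 replicate 3, 44 in WT ZT8 replicate 4, 18 in WT ZT16 replicate 2 and 12 in WT ZT20 replicate 5, all libraries standing apart, and at most 6 in any other WT library. Leaving out KO ZT12 replicate 5 gave 26 rows higher and 525 lower, and calls in 1 or both directions also arose without WT ZT0 replicate 2, WT ZT4 replicates 1 or 2, WT ZT20 replicate 1, KO ZT16 replicate 1 or KO ZT20 replicate 1.

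At ZT0, 187 rows were called different, 2 higher and 185 lower in KO. All lay just under the threshold, with a smallest adjusted p of 0.0498. WT ZT0 replicate 3, the deepest library, was the highest of the 5 WT libraries in 175 of the 185 lower rows. In these 185 rows the median was 973 CPM in that library, 36.4 CPM in the other 4 WT libraries and 29.2 CPM in the 5 KO libraries. Table row 24534 had a log2 fold change of -2.57 ± 0.56 and table row 11874 one of -4.71 ± 1.07 (SE), with 1005 and 1099 counts in WT ZT0 replicate 3 and at most 22 and 4 in any other ZT0 library. In the other direction, table row 18221 had 1.50 ± 0.44 and table row 25221 had 1.86 ± 0.55. Without WT ZT0 replicate 3 the count was 0, and it was 0 in 46 of the 60 fits that left out 1 library. DESeq2 called 183 rows, while library size alone as the scaling, the total count as a covariate and a fit of the 10 ZT0 libraries alone each gave 0. Of 18 alternative settings, 12 gave a count lower by over 1.5 times.

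At the other times 0 rows were called by edgeR. The counts at an unadjusted p under 0.05 were 155 at ZT4, 228 at ZT8, 788 at ZT12, 1336 at ZT16 and 268 at ZT20. By chance 301.5 are expected at each time, so those at ZT4, ZT8 and ZT20 lie under that number. DESeq2 on the same rows called 71 at ZT4, 134 at ZT8, 18 at ZT12, 174 at ZT16 and 27 at ZT20. With the 10 libraries of ZT16 fitted alone, edgeR called 857 rows; 4 of the 5 WT libraries and 0 of the 5 KO libraries at that time stood apart. In simulated counts of the same depth, 40 to 56 of 100 changes of 2 (log2) at a single time were recovered. Those simulated libraries lack the split seen in the real ones, and 100 changes of 4 (log2) were put into the same runs. The recovered share therefore does not measure how many real changes of that size would have been called.

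The number in the library name, 5 to 9, gave no comparison of the genotypes at the same time within 1 number. Numbers 5 and 6 held only WT libraries, 8 and 9 only KO libraries, and 7 held both genotypes at different times. The labels do not say what the number stands for. With the number as a factor, 1 row was called for the WT rhythm and 0 for the KO rhythm, the rhythm difference, the level, ZT0 and ZT4. The contrasts at ZT8, ZT12, ZT16 and ZT20 could not be estimated with it. The number and the genotype at those times cannot be told apart.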

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

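The fit with the library-name number as a factor was planned before the data were examined, and the thinning and the draws of random libraries were set down before their results were seen. The tests of the number and of genotype on the first component, and what the fit with the number and the splits of the samples would have to show, were set down after. In 48 groups tested for a library far from the others, 12 were found, where chance gives about 2.4. In 3 of the 12 the other libraries of the group were tied at 0 counts, so any count stood out there, and several of the 12 are the same library.

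Total counts had a far library in WT ZT0, replicate 3, at 1677090 against 359693 for the next, and in WT ZT8, replicate 4, at 532953 against 142656. The first component score was far from the other libraries of the group in WT ZT4 replicate 5 (38.9), WT ZT8 replicate 4 (87.7), WT ZT20 replicate 5 (95.3) and KO ZT12 replicate 5 (82.5). In log2 CPM, table row 20125 was low in KO ZT12 replicate 5, at 5.50 against 7.48 for the nearest. Table row 25624 was far above the others in log2 CPM in KO ZT4 replicate 3 (8.48, 92 counts) and KO ZT12 replicate 5 (5.60, 11 counts). In WT ZT4 replicate 2 (4.14, 1 count), WT ZT8 replicate 4 (5.59, 15 counts) and KO ZT8 replicate 4 (6.09, 3 counts) the other 4 libraries had 0 counts of it, so those values carry no more than the counts given.

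The libraries fell into 19 and 39 by their overall profile. Totals ran from 68728 to 1677090 counts in the 19 and from 40959 to 487352 in the 39. After every library was thinned to 40959 counts, all 19 of the 19 still lay above every other library on the first component. This argues against the number of counts sampled as the cause. A cause that sets both the profile and the total was not tested, since thinning cannot remove it. Libraries of both kinds occur in all 5 of the library-name numbers, which argues against that number as the whole cause. Both kinds also occur in each of the 2 genotypes, which argues against genotype as the whole cause, while a part played by it stays open, since the permutation p of 0.0905 does not decide. RNA of another tissue or cell type, or a mislabelled sample, was not tested, because the rows have no names to set marker lists against.

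Rhythms differed between the genotypes by test in 32 rows, led by table row 25624 at an adjusted p of 0.000795. Of 100 splits of the genotypes within ZT, the real one included, 18 gave as many, and the highest of the others gave 1330 rows, far above the real count, which points to a structure of the samples. Chance can therefore not be excluded for this count. None of the 32 rows was called without the 19 libraries standing apart, but 71 of 100 draws that left out as many random libraries per group also called 0 of them. The median draw lay at that floor of 0 too, so a count equal to it speaks neither for nor against these libraries as the cause. In table rows 25624 and 22108 the highest counts lay in libraries standing apart. The other rows of the 32 were not looked at library by library. With the library-name number as a factor 0 rows were called, and since that number mostly follows time and genotype the 2 cannot be told apart. A dependence of these rhythms on the liver clock stays open as well.

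The other counts were set against the same kind of splits. For the 17 rows rhythmic in WT, 39 of 100 splits of the times gave as many (highest of the others 1087), and for the 41 in KO, 18 of 100 did (highest 684). For the 187 rows at ZT0, 61 of 100 splits gave as many (highest 1880). Chance can be excluded for none of these 3 counts. Where the real count was 0, for the level and at ZT4, ZT8, ZT12, ZT16 and ZT20, all 100 of 100 splits reach it by construction, so the splits say nothing there. The highest counts in other splits were 432 rows higher and 469 lower for the level, and 0, 1, 1423, 1 and 1 at those times.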

How the results depend on the processing

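The alternatives with libraries standing apart or under 10000 counts left out, with principal components, or with rows seen in 90% of libraries were chosen after seeing the data; the others were set before. Counts are given in the order WT rhythm, KO rhythm and rhythm difference (17, 41 and 32 as reported), then ZT0 (187); counts not given stayed within 1.5 times, and the cause of a change was not tested unless stated. DESeq2 size factors gave 66 for the KO rhythm. Library size alone gave 11, 62, 76 and 0 at ZT0. No low-count filter, which tests 25438 rows, gave 281, 1067, 686 and 0 at ZT0, with the level higher in 38 and lower in 1070. A CPM of at least 1 in 30 libraries gave 7, 7 and 11. DESeq2 gave 65, 6 and 97, with 71 at ZT4, 134 at ZT8, 18 at ZT12, 174 at ZT16 and 27 at ZT20. The library-name number gave 1, 0, 0 and 0 at ZT0. The total count as a covariate gave 255 for the KO rhythm, 141 for the difference and 0 at ZT0. Without libraries under 51632 counts the counts were 8, 6 and, at ZT0, 0. Time as a factor gave 35, 16 and 0. Tested among the 51 rows rhythmic in WT or KO, the difference was called in 43, which are mostly other rows, since 1 of the 32 was rhythmic in either; choosing rows by a rhythm in 1 genotype favours a difference. Choice by the Bayesian information criterion gave 487 for the difference, of which 437 were rhythmic in WT alone, 46 in KO alone and 4 in both with different rhythms. Each ZT alone gave 0 at ZT0 and 857 at ZT16. An adjusted p under 0.01 gave 1, 1, 1 and 0 at ZT0.

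Without the 2 libraries under 10000 counts the KO rhythm had 26 and ZT0 297, including all 187; with the rows chosen again the KO rhythm had 86, the difference 66 and ZT0 0. Without those and the 19 standing apart, the counts were 37, 132, 15 and 0 at ZT0, and with the rows chosen again 11, 8, 0, 0 at ZT0 and 3 at ZT12. The first principal component of all 60 libraries as a covariate gave 548, 216, 392, 787 at ZT0 and 40 at ZT16. The first 3 gave 62 for the WT rhythm, 58 for the difference, the level higher in 21 and lower in 1, 111 at ZT0 and 4 at ZT4. Without the 2 libraries under 10000 counts and with only rows seen in 90% of the others, the counts were 2, 2 and 0.

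The replicate block gave 2, 3, 1 and 0 at ZT0. No pairing of the libraries by replicate number was seen. Of 308 pairs with the same number, 120 had a correlation of deviations over 0.1, and 15 of 58 libraries correlated best with one of their own number. The mean correlation was 0.0371 for the same number (lowest -0.720) and -0.00397 for other numbers. The deviations still hold the split of the libraries within groups, so a pairing could have been missed.

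Leaving out 1 library at a time gave 6 (WT ZT12 replicate 2) to 47 (WT ZT0 replicate 4) for the WT rhythm, 7 to 732 (KO ZT12 replicate 5) for the KO rhythm, and 1 (WT ZT12 replicate 2 or KO ZT4 replicate 3) to 711 (KO ZT12 replicate 5) for the difference. The level ranged from 0 to 26 higher and 0 to 525 lower, both highest without KO ZT12 replicate 5. ZT0 ranged from 0 to 611 (WT ZT0 replicate 4), ZT8 from 0 to 1 and ZT12 from 0 to 4, while ZT4, ZT16 and ZT20 stayed at 0. Counts moved by over 1.5 times in 12, 33, 32 and 53 of the 60 fits for the WT rhythm, the KO rhythm, the difference and ZT0. Of the 732 rows called for the KO rhythm without KO ZT12 replicate 5, 109 were called without the libraries standing apart, and of the 711 for the difference 4 were. The median absolute correlation with the first component score was 0.734 in the 732 rows and 0.749 in the 711, against 0.462 over all tested rows. Table row 20125 kept both rhythms in 60 of 60 such fits and in 14 of 15 other settings of the same model, with adjusted p of 0.055 in WT and 0.122 in KO with the library-name number.

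Amplitude and phase with a threshold of 0.01 rest on 1 row, with a log2 amplitude ratio of 0.34 and a peak difference of 1.40 h (19 and 13 of 100 draws as large). Under TMM, DESeq2 size factors and library size alone, the median log2 fold change of all rows at ZT0 was -0.10, -0.10 and 0.15, and the calls at ZT0 split into 2 higher and 185 lower, 3 and 261, and 0 and 0. The gene list, named gene and marker results had no value, since rows have no names; the settings for normalized values did not apply to counts. The median count per tested row was 0 in the shallowest library and at most 64 in any, which limits what can be detected in rows of low counts. Without the 2 libraries under 10000 counts the WT rhythm had 14, and the level and ZT4 to ZT20 stayed at 0.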

Other observations

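The fit with the library-name number as a factor was planned before the data were examined. What it would have to show, and the other tests in this part, were set down after results they measure, or close relatives of them, had been seen.

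Chance was tested for the set of rows rhythmic in both genotypes and for the row that leads it. Of 100 splits of the times within genotype, 35 gave at least the 7 rows called in both (highest of the others 43), so chance is not excluded for the count. Table row 20125 was the single row with the smallest p in both genotypes. Of 100 splits, the real one included, 3 held a row with as small a p. That p was 1.03e-07 (edgeR quasi-likelihood test), the larger of its WT and KO values, against 5.68e-08 in the most extreme other split. The share of splits lies under 0.05, a bound set down after results had been seen. With 100 splits it lies too near that bound to exclude chance for this row. Without the libraries standing apart its larger adjusted p was 0.00538, which argues against those libraries as the cause. With the library-name number as a factor it was 0.122. The number mostly follows time within a genotype, so that fit does not decide. Number 7 holds all KO libraries at ZT0 and ZT4. The row had 7.19 to 33.4 CPM at ZT0 and 52.6 to 336 CPM at ZT4. Number 8 holds all KO libraries at ZT8 and ZT16, with 112 to 240 CPM and 21.7 to 186 CPM, which overlap. For this row in KO, the values within number 7 argue against the number as the whole cause. Whether this row has a daily rhythm in fat that does not need the liver clock stays open, since chance and a part played by the number are not excluded.

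Peak times were compared between genotypes, since WT and KO libraries are separate. Over all 60 libraries, 4 of the 17 rows rhythmic in WT had a KO peak within 3 h of the WT peak, and 45 of 100 shuffles of the KO times gave as many (highest of the others 14), so that test does not decide. In the 39 libraries left without those standing apart and those under 10000 counts, 9 of the 11 rows rhythmic in WT had a KO peak within 3 h. That set holds 1 WT library at ZT12 and 1 at ZT16, so the WT rhythms and peaks near those times rest on single libraries. Of 100 shuffles, only the real one (1) reached that number, and the highest of the others was 8. Table row 7370 peaked at 11.6 h in WT and 0.379 h later in KO, with amplitudes of 1.55 and 1.17 (log2), and table row 20125 at 8.91 h and 8.76 h, with 1.83 and 1.77. Over the 11 rows the KO amplitude ran from 0.16 in table row 14670 to 1.77 in table row 20125. Most of the 11 were not called rhythmic in KO, so many of the KO peak times come from weak fits. The median amplitude of the 11 rows was 0.84 in WT and 0.40 in KO, but over the 8 rows rhythmic in KO it was 0.72 and 0.74, so the genotype a row was chosen in sets part of that gap. The test of the rhythm difference called 0 rows there. These values may reflect a small set of rows with the same timing in both genotypes, a hypothesis found and tested on the same data, after many other sets of libraries and rows had been looked at.

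Among 1133 neighbouring pairs with a mean of at least 50 CPM, 90 had a correlation across the 58 libraries over 0.9, against 1 of 715 pairs lying 100 lines apart. The median correlation was 0.190 and 0.0394. These correlations are across libraries that fall into separate sets, and no explanation was tested.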
